A study of Homo sapiens with 6 samples.

How the data were processed

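RNA was measured in 6 libraries of H841, an established human small cell lung cancer line. Per the labels, H841 is a non-neuroendocrine line of the POU2F3 subtype, but POU2F3 had 0 counts in the control libraries. The 3 control libraries and the 3 libraries from cells given 200 mM trehalose for 12 h carry the replicate numbers 1 to 3. The labels do not say whether these are separate cultures, so the p-value of a gene measures only the spread between these 6 libraries. Camera at its preset correlation and Fisher's exact test take their spread over genes. Their p-values do not count libraries as the units. Per the labels' protocols, poly(A) mRNA was selected and made into strand-marked (dUTP) libraries, which were read as pairs on an Illumina NovaSeq instrument.

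Per the submitters' processing notes, the authors trimmed reads with cutadapt 1.9, aligned them with HISAT2 2.2.1 to hg38 and used StringTie 2.1.6. DESeq2 and edgeR are also named there, without a role. The annotation, the strand setting and the tool that counted reads are not given in the sources used here. Per the file headers, the deposited table gives an estimated count and an FPKM value per gene and library, for 36459 genes with hg38 coordinates. The authors' FPKM values are fragments scaled by gene length and library depth, with 2 decimals. The deposited expected counts are whole numbers that were not scaled between libraries. Their low values pile up at multiples of 4: the value 4 was 2.15 to 2.45 times as frequent as its neighbours, and the value 8 was 1.62 to 1.92 times. A count of 4 is read here as about 1 read pair, so the counts overstate the number of independent fragments. All rows named a gene, and 9550 carried an Ensembl identifier as the symbol. No comparison by the authors was used.

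Counts were used as deposited, since they were whole. Genes were kept by filterByExpr of edgeR 4.0.16 (minimum count 10, minimum total count 15), which left 21108 genes with 99.93% of all counts. Trehalose was compared with control by edgeR's quasi-likelihood test with TMM factors and a robust fit. P-values were adjusted over the tested genes by the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 are called changed. The common biological coefficient of variation was 0.256. A size threshold of 1 on the absolute log2 fold change gives the genes changed at least 2-fold. CPM values use the TMM-scaled library size, and values of a group are means over 3 libraries, in part with ± SD. Some log2 fold changes are given with a standard error (SE). It is the absolute log2 fold change divided by the square root of the test's F statistic.

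The test, the filters, 36 gene lists and most alternatives were chosen before the data were examined. The lists held 804 entries, of which 793 matched a symbol in the table. They were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were run beside it. Camera compares a list with the other genes. At the preset correlation its degrees of freedom come from the genes, and with an estimated correlation from the 6 libraries. A p-value with an estimated correlation can thus be larger even where the estimate is near 0. Fry tests whether a list's genes move on balance in one direction, and its mixed p-value whether they change in either direction, and neither compares the list with other genes. Named genes follow a rule fixed at the same time. It takes the 12 largest rises and 12 largest falls among called genes with a proper symbol, at least 5 CPM on average and groups that do not overlap. It adds the 4 members of each list with the smallest p, and 18 genes of prior interest. This gave 171 tested genes, of which 167 were called, and genes named outside the rule are marked in the text. KEGG pathways and GO terms with 15 to 300 tested members were examined after the gene results were seen.

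Shares of counts per library were compared by exact two-sided permutation tests, whose smallest possible p with 3 against 3 libraries is 0.1. A fold change against a control group at 0 is given as a lower bound, against a floor of 12 counts (3 read pairs) over the control group. With 1 to 3 read pairs in the control group, the ratio is given with a 95% counting interval. These floors and intervals cover counting error only. GC content and length came from GENCODE 29 transcripts, which 94.9% of the genes matched by identifier.

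The alternatives were a replicate block, each library left out in turn, no filter and a filter of at least 5 CPM in 3 libraries, RLE factors and total counts without factors, DESeq2 1.42.0 with its Wald test, limma-voom, limma on log2(FPKM + 1) and log2(FPKM + 0.1), and glmTreat against a fold of 1.2. Counts divided by 4 and a GC correction per library were added after seeing the data. Data were simulated with 200 changed genes among 21118 tested and a dispersion of 0.05 for every gene. There edgeR called 4.6% of the genes changed 1.5-fold, 36.4% of those changed 2-fold and 100% of those changed 4-fold, with 2 false calls. A list of 26 members shifted 2-fold was called, and 0 other lists were. The work was done in R 4.3.3 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.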

Results

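Poly(A) RNA was sequenced from 6 samples of H841 cells, 3 controls and 3 given 200 mM of the disaccharide trehalose for 12 h. The control libraries held 60107521, 59910077 and 62416120 counts, and the trehalose libraries 71469651, 57485404 and 58363885. The comparison asks which transcripts differ between H841 cells with and without trehalose. Coordinates are those of hg38 as listed with the counts, and all values below are from 3 libraries per group.

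The osmolyte transporter genes SLC5A3 and SLC6A6 and the sorbitol-making enzyme gene AKR1B1 rose in H841 cells with trehalose, at log2 fold changes of 3.40 (SE 0.19), 3.05 (SE 0.21) and 2.5 (SE 0.14). Of 24 immediate early genes 17 rose and 3 fell, with DUSP1 at 3.11 (SE 0.13), and of 13 replication-dependent histone genes 7 rose and 0 fell, with H3C2 at 6.29 (SE 0.28). Camera called both lists, but not with an estimated correlation (adjusted p = 0.240 with an estimated correlation for each, Benjamini-Hochberg). The estimates were 0 and −0.002, below the preset 0.01, so correlation between members does not explain these lost calls. With an estimated correlation camera also takes its degrees of freedom from the 6 libraries and not from the genes. The ribonucleotide reductase gene RRM2 (−1.48, SE 0.08) and the peroxisomal enzyme gene EHHADH (−3.47, SE 0.27) fell. Of 21108 genes tested with edgeR's quasi-likelihood test, 10864 changed, 5636 upward and 5228 downward, and with total counts without factors the majority turned, to 4871 upward and 5969 downward. At least 2-fold changes were found for 6107 genes, 3406 upward and 2701 downward, but 2958 upward and 3298 downward with total counts without factors. The groups did not overlap in 13211 (62.6%) of all tested genes, where chance gives 10%. The 2-fold count was 3172 with a filter of at least 5 CPM, and 2160 on log2(FPKM + 1), 917 upward and 1243 downward. Scaling by total counts without factors moved the median log2 fold change of all tested genes from 0.041 to −0.087.

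The first principal component held 70.8% of the variance of log2 CPM and separated the groups. The second held 11% and set trehalose library 1 apart from the other libraries of its group. More genes were above 0 in the trehalose libraries (28491 ± 394 on average) than in the controls (26132 ± 168). The exact two-sided permutation p of this difference was 0.1, the smallest that 3 against 3 can give.

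**Figure D1:**
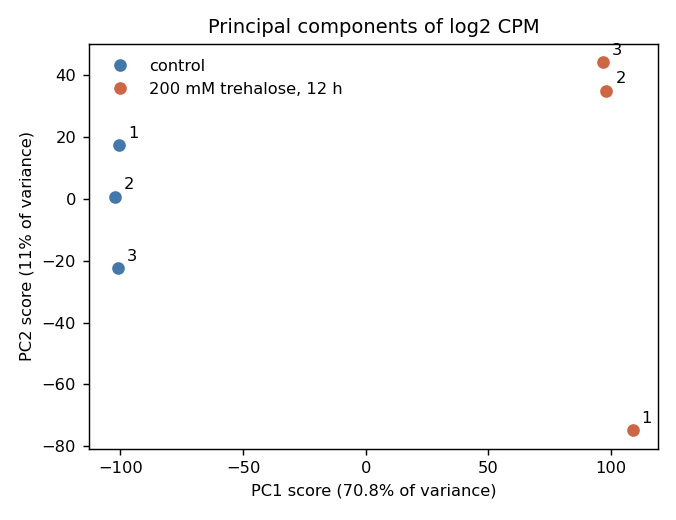
Scores of the 6 H841 libraries on the first and second principal components of log2 CPM (70.8% and 11% of the variance), with replicate numbers beside the points. Controls lie at −100.44 to −102.32 on the first axis and trehalose libraries at 96.77 to 108.85, with trehalose library 1 at −74.89 on the second axis.

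The 36 lists fixed beforehand were tested with camera at its preset correlation, and 4 were called, all upward, while 0 were called with an estimated correlation. By fry, 24 lists moved on balance in one direction and 35 changed in either direction. Since 51.5% of all tested genes changed, the count of 35 says little about these lists in particular. Member counts are over all tested genes. Adjusted over the list alone they were the same for 28 lists, and the other counts of the remaining 8 lists are given with each. A range after the counts of a list gives its higher and lower members over 17 alternative settings, where a count moved by over 1.5 times, and settings are given where the majority changed. Ranges of medians are over the same settings. The majority held in every one for 20 lists. The named genes MCOLN1, NFAT5, NFE2L2 and PGK1 overlap another expressed gene on the same strand, so their reads are uncertain.

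**Figure D2:**
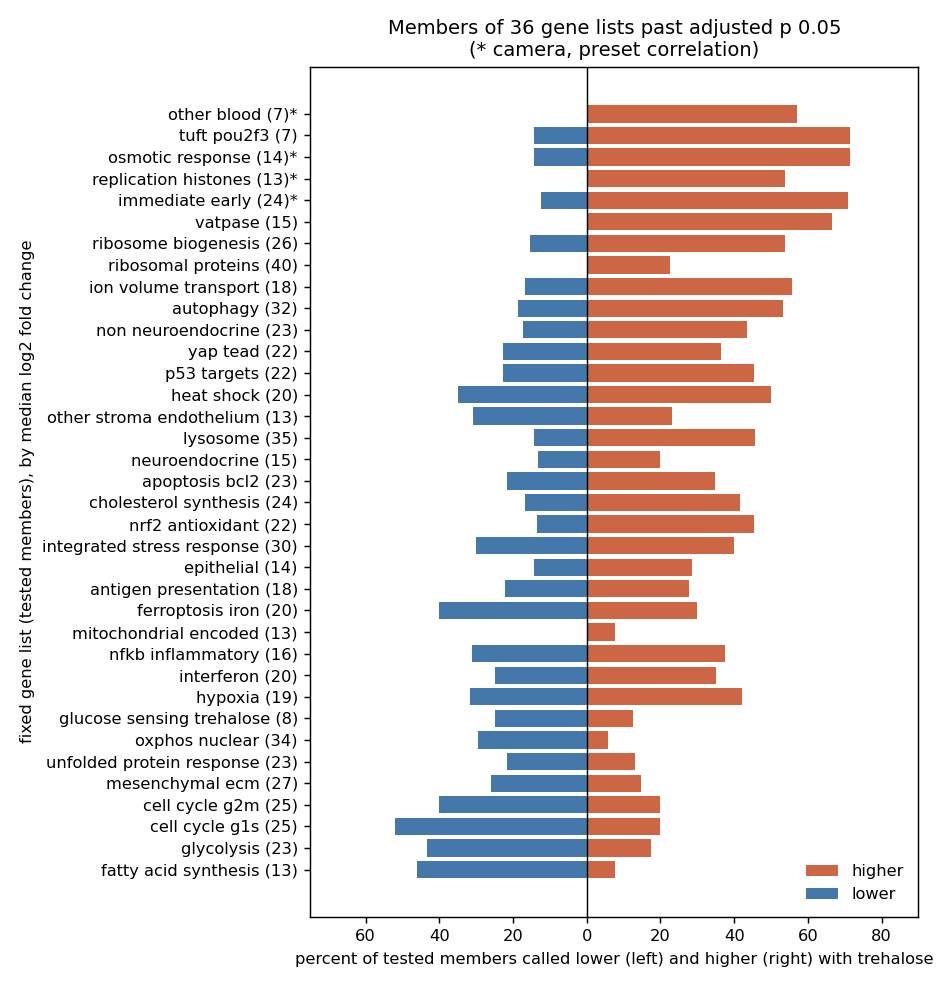
Bars give the percent of each list's tested members that were higher (right) or lower (left) with trehalose past an adjusted p of 0.05, with the number tested in parentheses and lists ordered by median log2 fold change. An asterisk marks the 4 lists called by camera, which had 53.8 to 71.4% of their members higher. The majority is lost or turns in at least 1 of 17 alternative settings in 16 lists: antigen presentation, BCL2 family, cholesterol, epithelial, iron, trehalose and glucose-sensing, chaperone, hypoxia, integrated stress response, interferon, neuroendocrine, NF-kB, non-neuroendocrine, fibroblast and endothelium, ribosomal protein and unfolded protein response.

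Of 14 tested genes known to respond to hypertonic medium, 10 rose and 2 fell (range 8 to 10 and 1 to 2), with a median log2 fold change of 1.74. Camera called the list with a Benjamini-Hochberg adjusted p = 0.0154, but not when correlation was estimated (adjusted p = 0.572 with an estimated correlation). SLC5A3, the sodium-coupled myo-inositol transporter (chromosome 21, 34073578 to 34106260), went from 42.7 ± 5.58 to 452 ± 98.0 CPM. It overlaps MRPS6 on the same strand, so its reads are uncertain. AKR1B1, the aldose reductase that makes sorbitol (chromosome 7, 134442356 to 134459284), went from 164.5 ± 4.26 to 933 ± 170 CPM. SLC6A6, the taurine transporter (chromosome 3, 14402576 to 14489349), went from 21.7 ± 3.09 to 180.5 ± 44.9 CPM. The edgeR quasi-likelihood adjusted p-values (Benjamini-Hochberg) of these genes were 2.73e-05, 2.76e-05 and 5.01e-05. SGK1, a kinase that regulates sodium transport, rose by 1.56 (SE 0.10) on the log2 scale, and NFAT5, the transcription factor of the tonicity response, by 1.38 (SE 0.31). The members that fell, HSPA4L (−2.26) and CYP3A5 (−0.64), lie outside the naming rule and were named after their values were seen.

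**Figure D3:**
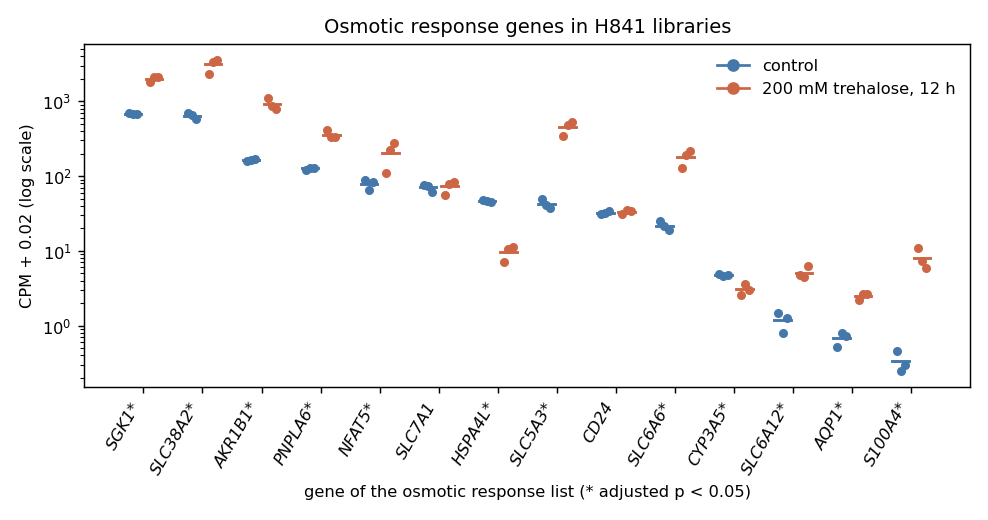
CPM plus 0.02 of the 14 tested osmotic response genes in each H841 library (log axis, points) with the group mean (line), ordered by control level. SLC5A3 and AKR1B1 reach means of 452 and 933 CPM with trehalose, against 42.7 and 164.5 CPM in controls, and asterisks mark adjusted p under 0.05.

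Ion transport and cell volume genes were not called as a list (camera, Benjamini-Hochberg adjusted p = 0.161), with 10 of 18 members higher and 3 lower. ATP1B1, a subunit of the sodium pump, rose by 2.73 (SE 0.11) on the log2 scale. LRRC8A, a subunit of the volume-regulated anion channel, rose by 1.41, while STK39, a kinase that activates chloride cotransporters, fell by 1.37.

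Immediate early genes, which code for early transcription factors and their feedback phosphatases, rose in 17 of 24 cases and fell in 3, with a median log2 fold change of 1.46. Camera gave the list a Benjamini-Hochberg adjusted p = 0.000744 (adjusted p = 0.240 with an estimated correlation). DUSP1, a phosphatase of MAP kinases, went from 12.5 ± 1.58 to 108.0 ± 6.63 CPM, and MYC from 90.1 ± 3.16 to 267 ± 19.2 CPM. IER5 and the nuclear receptor gene NR4A2 rose by 2.33 and 3.51 on the log2 scale. The members that fell were EGR1 (−2.31), FOS (−0.69) and DUSP6 (−0.51), named after their values were seen.

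The other stress lists were not called by camera. NF-kB targets had 6 of 16 members higher and 5 lower (range 4 to 6 and 2 to 5, with equal counts in 7 settings), with a mean of 0.78. Their median was −0.03 (range −0.19 to 0.70) and above 0 in each of the 6 fits without 1 library. NFKBIA, which codes for an inhibitor of NF-kB, and IER3 rose by 3.17 and 3.69 on the log2 scale. TNF had 0 counts in the controls and was at least 11.9-fold higher with trehalose, at 0.731 CPM. TNF lies 16.7 kb downstream of the expressed gene NFKBIL1 on the same strand. Among p53 targets and cell cycle inhibitors, 10 of 22 rose and 5 fell (range 6 to 12 and 3 to 6), with CDKN1A at 1.78 (SE 0.18), SESN1 at 1.94 and TP53I3 at −1.18. Of 20 chaperone genes, 10 rose and 7 fell, or 7 and 7 of 19 on FPKM. HSPA1A and HSPA1B rose by 1.5 and 1.46, and since they are near-identical copies, the split of reads between them is uncertain. The integrated stress response list had 12 of 30 members higher and 9 lower, or 10 and 10 with total counts without factors and, of 27, on FPKM. ATF4, its transcription factor, went from 245.8 ± 10.4 to 650 ± 147 CPM. The amino acid transporter gene SLC3A2 rose by 1.40, while the serine synthesis genes PSAT1 and PSPH fell by 1.25 and 1.53 on the log2 scale. In the unfolded protein response list, 3 of 23 members rose and 5 fell (3 and 3 adjusted over the list alone, range 3 to 7 and 2 to 12). More rose than fell in 4 of the 17 settings, with 6 and 3 after a GC correction, counts were equal in 6, and without trehalose library 1 they were 7 and 12. Its members DNAJB9 and HERPUD1 rose by 1.51 and 1.2, and ATF6 and PDIA4 fell by 1.76 and 1.02. Of 19 hypoxia genes, 8 rose and 6 fell (9 and 6 adjusted over the list alone, and 7 and 8 of 18 on FPKM), with LOX at 2.23 and PDK1 at −2.07. Their median was −0.08 (range −0.21 to 0.22) and their mean 0.21, with camera upward.

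Replication-dependent histone genes, whose mRNA mostly lacks a poly(A) tail, rose in 7 of 13 cases and fell in 0, with a median log2 fold change of 1.57 (range 1.43 to 2.87, the highest over 8 genes with at least 5 CPM). Camera gave a Benjamini-Hochberg adjusted p = 0.00113 (adjusted p = 0.240 with an estimated correlation). H3C2 (chromosome 6, 26031589 to 26032099) went from 0.526 ± 0.149 to 41.3 ± 9.0 CPM, H2BC12 from 15.5 to 108.8 CPM and H2AC6 from 9.60 to 49.0 CPM. Histone genes resemble one another, so the split of reads between copies is uncertain. Mitochondrial ribosomal RNA made up 0.986 ± 0.0964% of counts with trehalose and 0.589 ± 0.0155% in controls (exact permutation p = 0.1, the smallest possible).

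The G1/S and DNA replication list moved the other way, with 13 of 25 members lower and 5 higher (range of higher 3 to 6, of lower 9 to 15) and a median log2 fold change of −0.32. Camera did not call it (Benjamini-Hochberg adjusted p = 0.110), except downward with a GC correction (0.0241) and with no filter (0.0158), in a range of 0.0158 to 0.509 over 14 camera alternatives. The ribonucleotide reductase genes RRM2 and RRM1 fell by 1.48 and 1.43 on the log2 scale, and the helicase subunit gene MCM6 by 1.0. In the G2/M list 10 of 25 fell and 5 rose (11 and 5 adjusted over the list alone, range of higher 4 to 7, of lower 6 to 12). CCNB2 and HMMR fell by 1.14 and 1.9, while CDC20 and PLK1 rose by 0.95 and 0.64.

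Of 35 lysosome genes 16 rose and 5 fell (range 12 to 18 and 4 to 10, with 16 and 10 without trehalose library 1), and of 32 autophagy genes 17 rose and 6 fell (17 and 7 adjusted over the list alone). Camera called neither list, except autophagy with at least 5 CPM (0.0476, range 0.0476 to 0.509 over 14 camera alternatives). In the GO term lysosome organization, tested after the gene results were seen, 7 of 48 genes rose and 22 fell, without a camera call (Benjamini-Hochberg adjusted p = 0.244). MCOLN1, the lysosomal calcium channel, went from 25.8 to 165 CPM, and the chloride transporter gene CLCN7 rose by 1.64 (SE 0.12) on the log2 scale. MAP1LC3B, which marks autophagosomes, and SQSTM1, a cargo receptor, rose by 1.46 and 1.08. Of the transcription factors of these genes, TFE3 rose by 1.55 and TFEB fell by 1.15. Subunits of the lysosomal proton pump rose in 10 of 15 cases and fell in 0 (range 5 to 12 and 0 to 1), with ATP6V0B at 1.79 and ATP6V0A1 at 0.80. The pump list missed the threshold (camera, Benjamini-Hochberg adjusted p = 0.0576). It passed at 0.0347 without trehalose library 1, at 0.0280 without trehalose library 3, at 0.0230 with at least 5 CPM, at 0.0395 with counts divided by 4 and at 0.0241 with a GC correction. Over its 14 camera alternatives the adjusted p was 0.0230 to 0.879.

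Among NRF2 targets and antioxidant enzymes, 10 of 22 rose and 3 fell (range 6 to 10 and 1 to 7, with 10 and 7 without trehalose library 1). HMOX1, the heme oxygenase gene (chromosome 22, 35380361 to 35394214), went from 32.4 ± 0.844 to 329 ± 41.4 CPM, a log2 fold change of 3.34 (SE 0.12; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 1.27e-05). NFE2L2, which codes for NRF2 itself, rose by 0.99, and the peroxidase gene PRDX1 by 1.37. SLC7A11, the cystine transporter, fell by 1.78 on the log2 scale. Of 20 genes of iron handling and lipid peroxidation, 6 rose and 8 fell (range 6 to 9 and 4 to 10, with more higher than lower in 3 settings and equal counts in 2), with the polyamine acetyltransferase gene SAT1 at 3.35 and DHODH at −1.35. Their median was 0.004 (range −0.17 to 0.09) and their mean 0.224, while camera pointed downward. TREH, which codes for the enzyme that splits trehalose, had 3 counts in 1 control and 3 in 1 trehalose library, too few to test. Of 8 trehalose and glucose-sensing genes 1 rose and 2 fell (range 1 to 3 and 0 to 3, with more higher than lower in 5 settings and equal counts in 5). SLC2A8, a glucose transporter, was called at −0.40, but in 5 of the 6 fits without 1 library (all except trehalose 1) it was not, at −0.50 to −0.35 over the 6, nor against a fold of 1.2. MLXIPL was called at −1.19 and lost the call in 4 fits (without control 2, control 3, trehalose 2 or trehalose 3), at −1.73 to −0.92 over the 6. TXNIP did not pass (1.47, SE 0.63), but passed without control library 1 and without trehalose library 1, at 1.06 to 2.16 over the 6 fits. The median of this list was −0.09 (range −0.22 to 0.10) and its mean 0.002.

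Camera called none of the metabolic lists in the planned fit. Of 23 glycolysis genes 10 fell and 4 rose (11 and 4 adjusted over the list alone), with the phosphofructokinase gene PFKM at −1.92, PGK1 at −0.77 and the glucose transporter gene SLC2A3 at 1.52. Of 13 fatty acid synthesis genes 6 fell and 1 rose (range of higher 0 to 3, of lower 5 to 8), with ACSL3 at −1.18 and the desaturase gene FADS1 at −1.02. Of 34 nuclear-encoded respiratory chain genes 10 fell and 2 rose (range of higher 0 to 2, of lower 10 to 22), among them ATP5PB (−1.07) and SDHC (−0.96). Without trehalose library 1 22 fell. The median of −0.15 was −0.36 without that library, −0.04 without trehalose library 2, −0.08 without control library 3 and 0.02 without trehalose library 3. That list had a camera Benjamini-Hochberg adjusted p = 0.117, but passed at 0.00387 without trehalose library 1 and at 0.0232 with no filter, with 0.00387 to 0.883 over its 14 camera alternatives. With no filter camera also called glycolysis (0.0403, range 0.0403 to 0.879) and fatty acid synthesis (0.0158, range 0.0158 to 0.879) downward. Of 13 mitochondrially encoded mRNAs 1 rose, MT-ND1 at 0.86, and 0 fell (range 1 to 3 and 0), with a median of −0.01 (range −0.15 to 0.09) and a mean of 0.08. MT-ND2 (0.18) passed without trehalose library 1 and with a GC correction, at 0.11 to 0.25 over the 6 fits without 1 library. MT-ND3 (0.545) passed without trehalose library 3, with DESeq2 and with a GC correction, at 0.247 to 0.682 over those 6 fits. MT-ND6 (0.28) passed without trehalose library 3, at 0.173 to 0.394. All mitochondrial genes together took 7.42 ± 0.252% of counts in controls and 7.48 ± 0.464% with trehalose (exact permutation p = 1). Cholesterol synthesis genes rose in 10 of 24 cases and fell in 4 (range 5 to 12 and 4 to 9), with INSIG1 at 1.6 and SQLE at 0.91. The counts were 7 and 7 with total counts without factors, 6 and 8 on FPKM and 12 and 9 without trehalose library 1.

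Ribosome biogenesis genes rose in 14 of 26 cases and fell in 4 (15 and 4 adjusted over the list alone, range 13 to 17 and 1 to 5; camera, Benjamini-Hochberg adjusted p = 0.0867). With at least 5 CPM camera called this list (0.0314, range 0.0314 to 0.512 over 14 camera alternatives). NOP2, an rRNA methyltransferase, went from 136 to 476 CPM, and WDR12 fell by 0.84 on the log2 scale. Of 40 ribosomal protein genes 9 rose and 0 fell (range 0 to 17 and 0 to 4), but 0 passed adjusted over the list alone. Without control library 1 or 2 0 passed, and without trehalose library 1 13 rose and 4 fell, with a median of 0.07 in place of 0.45 (range 0.07 to 0.60). Their camera Benjamini-Hochberg adjusted p was 0.0867. It was 0.0345 without trehalose library 2, 0.00944 without trehalose library 3 and 0.0314 with at least 5 CPM, with 0.00944 to 0.883 over 14 camera alternatives. The named members RPLP1 (1.04), RPLP0 and RPS19 each lost the call without control 1 and without control 2. All except RPLP1 also lost it without control 3, and their log2 fold changes were 0.38 to 1.25 over the 6 fits. RPLP0 and RPS19 were also not called on FPKM, nor RPLP0 against a fold of 1.2.

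POU2F3, for which the labels name the subtype of the line, had 0 counts in all 3 controls, while YAP1 was at 280 ± 28.7 CPM there. The control counts of POU2F3 thus go against the subtype that the labels give. POU2F3 was at least 8.7-fold higher with trehalose, at 0.559 CPM. It lies 6.31 kb downstream of the expressed gene OAF on the same strand. Of 18 tuft cell genes of the POU2F3 subtype 7 passed the count filter. Of these 5 rose and 1 fell (range 2 to 6 and 0 to 2 over 14 settings, camera Benjamini-Hochberg adjusted p = 0.117). Members near 0 in controls, such as POU2F3, passed the filter only through their trehalose counts. SH2D6, with 6, 17 and 20 counts in controls and 0 in each trehalose library, was left out. With no filter 5 of 16 rose and 2 fell. KIT was 25.2 times as high (95% counting interval 6.6 to 214), at 1.09 CPM with trehalose, and AVIL rose to 2.06 CPM. AVIL lies 1.19 kb downstream of the expressed gene CTDSP2 on the same strand. The neuroendocrine factor gene NEUROD1 had too few counts to test. Neuroendocrine genes rose in 3 of 15 cases and fell in 2 (range 2 to 4 and 2 to 4, with equal counts in 6 settings), with CHGA at 1.95 and BEX1 at −1.2. Non-neuroendocrine genes rose in 10 of 23 cases and fell in 4 (range 5 to 12 and 4 to 6, with 5 and 5 on FPKM), with the receptor gene EPHA2 at 1.99 and NOTCH3 at −1.23. YAP1 was called at 0.54 (280 to 406 CPM). It was not called in 5 of the 6 fits without 1 library (all except trehalose 1), at 0.44 to 0.71 over the 6, nor with total counts without factors, on FPKM or against a fold of 1.2. YAP1 and TAZ targets rose in 8 of 22 cases and fell in 5 (range 7 to 13 and 5, with 13 and 5 without trehalose library 1), with PTPN14 at 1.68 and the receptor gene AXL at −1.47.

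Of 27 mesenchymal and matrix genes 4 rose and 7 fell (4 and 5 adjusted over the list alone, range 3 to 5 and 5 to 11). Its transcription factor genes TWIST1 and SNAI1 rose by 2.17 and 2.25, and the integrin gene ITGA5 fell by 1.2. The median of this list was −0.19 (range −0.32 to −0.05) and its mean 0.072, and camera pointed downward where fry pointed upward. Epithelial genes rose in 4 of 14 cases and fell in 2 (range 1 to 5 and 0 to 5), or 3 and 4 with total counts without factors, 1 and 3 of 7 on FPKM and 5 and 5 without trehalose library 1. Their member CLDN4 went from 0.865 to 22.9 CPM, a log2 fold change of 4.72, or 5.38 without control 3. OVOL1 was at least 25.7-fold higher, from 0 counts to 2.84, 0.901 and 0.909 CPM, with trehalose library 1 the highest. In the BCL2 family and caspase list 8 of 23 rose and 5 fell (range 6 to 9 and 3 to 7), or 7 and 7 with total counts without factors and, of 20, on FPKM, with BCL2L11 at 1.79 and CASP9 at −0.82. Antigen presentation genes rose in 5 of 18 cases and fell in 4 (range 3 to 6 and 2 to 5, with fewer higher than lower in 6 settings and equal counts in 4). HLA-E was at 1.36 and PSMB9 at −1.80, and the list had a median of 0.016 (range −0.213 to 0.303) and a mean of −0.174. Interferon-stimulated genes rose in 7 of 20 cases and fell in 5 (range 3 to 7 and 4 to 8, with 6 and 8 without trehalose library 1, 3 and 5 of 11 on FPKM and equal counts in 2 settings), with IRF1 at 0.94 and OAS3 at −1.96. Their mean was 0.26 and their median −0.06 (range −0.34 to 0.29), which was above 0 without control library 3, trehalose library 2 or trehalose library 3.

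Of 7 tested blood and immune cell markers 4 rose and 0 fell, with a median log2 fold change of 3.14 (2.195 without trehalose library 2, 3.998 without control library 1, and 5.60 over 4 genes with counts divided by 4, the highest of the settings). Camera gave a Benjamini-Hochberg adjusted p = 0.0232 (adjusted p = 0.509 with an estimated correlation). The list has 15 members, and with no filter 5 of 12 rose and 0 fell, with a median of 2.77. CD14 went from 0.0742 ± 0.0802 to 10.8 ± 3.32 CPM, and ITGAM was at least 136-fold higher, from 0 counts to 8.38 CPM. CD14 lies 5.07 kb downstream of the expressed gene NDUFA2 on the same strand. The hemoglobin genes HBA1 and HBA2, near-identical copies with uncertain reads, reached 8.37 and 7.48 CPM. Of 13 markers of fibroblasts, muscle and endothelium 3 rose and 4 fell (range 0 to 4 and 3 to 4, with equal counts in 3 settings and 4 and 3 with a GC correction), with PDGFRB at −1.64 and CNN1 at −1.85. The medians of lists with a member at 0 in all controls were the same with that member at its bound.

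Among the 12 largest rises, PEDS1-UBE2V1, a readthrough gene that shares exons with its neighbours, was at least 1539-fold higher, from 0 counts to 95.1 ± 40.9 CPM. Its call was lost without trehalose library 1 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0634, and 6.73e-28 to 0.0634 over 18 alternatives). RAB17, a small GTPase gene (chromosome 2, 237574322 to 237591071), was at least 421-fold higher, from 0 counts to 26.3 ± 5.64 CPM. SELPLG was 329 times as high (95% counting interval 102 to 1981), and WNT7B, a secreted signalling protein gene, went from 1.67 to 59.2 CPM. The others were ADORA2A, CD14, OVGP1, H3C2, RRAD, SMPD3, PYGM and P2RY11, with log2 fold changes from 4.77 to 7.26. ADORA2A and P2RY11 lost the call with limma-voom. ADORA2A varied between trehalose libraries 1, 2 and 3, at 37.7, 30.7 and 2.43 CPM. It lies 0.14 kb downstream of the expressed gene SPECC1L on the same strand. P2RY11 rests on trehalose library 3 (39.0 CPM against 4.56 and 4.61), falls to 2.96 without it, and overlaps an expressed gene on the same strand, so its reads are uncertain. Without 1 control library CD14 was at 8.33 (control 2) or 6.57 (control 3), RRAD at 5.57 (control 2) or 7.19 (control 3), OVGP1 at 7.48 (control 3) and SELPLG at 8.98 (control 1). Of these 12 genes, 7 were below 0.5 CPM in the controls, and 7 had an expressed gene ending within 20 kb upstream on the same strand.

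The largest falls were in EMILIN3, a matrix protein gene (chromosome 20, 41359962 to 41366818), which went from 20.2 ± 2.05 to 1.43 ± 0.258 CPM, and in ZMAT1 (−3.70) and EHHADH (−3.47), an enzyme of peroxisomal fatty acid oxidation. PRELID2, CCDC113, GPRASP1, SPEF2, MSH5-SAPCD1, GPRASP2, IPP, ASTN2 and BTN3A1 followed, at −3.45 to −3.02. MSH5-SAPCD1, GPRASP1 and GPRASP2 overlap other expressed genes on the same strand, so their reads are uncertain.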

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

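Counts divided by 4, the GC correction and the test over every listed near-silent gene were chosen only after the results were seen. With the replicate block 8678 genes changed, 5464 at least 2-fold, and 4 lists were called. The series title calls the groups paired, but no label says that the numbers mark a shared culture or day. Same-numbered libraries deviated from their group means with correlations of −0.386, 0.019 and −0.391 across genes, and no library correlated best with its own number. With 3 libraries per group, these correlations cannot decide whether the numbers mark pairs. Leaving out 1 library gave 8972 to 12843 changed genes, the most without trehalose library 1, 5791 to 6419 of at least 2-fold, and 4 to 6 lists. The count of changed genes stayed within 1.5 times 10864 in all 18 alternatives, and every gene called in both fits kept its direction. The count of at least 2-fold changes (6107) was 3172 with at least 5 CPM in 3 libraries, where 12190 genes were tested, 2160 on log2(FPKM + 1) and 3555 on log2(FPKM + 0.1), where 13086 genes were tested, in another unit and with another tool. On log2(FPKM + 1), 3204 genes were higher and 4933 lower, against 5636 and 5228. The FPKM fits used no TMM factors, as with total counts without factors (4871 higher and 5969 lower). These settings are thus not independent checks. For FPKM the part of other causes was not tested. Lists called (4) were 8 with no filter, 8 with at least 5 CPM, 0 with an estimated correlation and 24 by fry, which asks another question; for the filters the cause was not tested. The 4 called lists lost the call only with the estimated correlation among the 15 alternatives. That estimate was 0 for the immediate early list and −0.002 for the histone list, against a preset of 0.01. It was 0.14 for the osmotic list and 0.085 for the blood markers. For the first pair, correlation between members is thus not why the call was lost. With an estimate, camera also takes its degrees of freedom from the libraries and not from the genes. For the osmotic and blood lists the part of each in the lost call cannot be told apart. The difference in mitochondrial share (0.059 percentage points) was 0.074 over genes with a symbol and −0.177 to 0.287 without 1 library. The tuft cell list could not be tested with at least 5 CPM or with counts divided by 4. Of the 167 called named genes 10 lost the call without 1 library (8, 8 and 7 genes without control 1, 2 and 3, and 2, 4 and 3 without trehalose 1, 2 and 3), 8 with the block, and 0 reversed in any alternative. In the simulation edgeR called 36.4% of 2-fold changes, but with 200 changed genes and the same dispersion for every gene. In the real data 10864 genes were called, which loosens the adjusted cutoff. That share therefore does not give the power of this comparison, though changes of that size or less may still be missed. In the real data 9319 genes passed a test against a fold of 1.2.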

Other observations

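KEGG pathways (301 tested) and GO terms (2556 tested) were chosen for a test only after the gene results were seen, as were the osmotic pressure, blood cell and S phase tests and the wider near-silent test; the splits, GC, readthrough, background and poly(A) tests had their bounds set before their own results were seen. Camera at its preset correlation called 34 pathways, 4 upward and 30 downward, and 71 GO terms, 26 upward and 45 downward, and 0 of either with an estimated correlation. The genes named here were picked after their values were seen. Peroxisome genes fell in 49 of 74 cases and rose in 6, with a median log2 fold change of −0.81 (camera, Benjamini-Hochberg adjusted p = 9.72e-05, and adjusted p = 0.557 with an estimated correlation). The peroxin gene PEX3 fell by 1.41, and the oxidation enzyme gene ECI2 by 2.03. Valine, leucine and isoleucine degradation genes fell in 33 of 46 cases and rose in 2, and Fatty acid degradation genes fell in 21 of 36 and rose in 1 (adjusted p = 9.72e-05 and 0.000377 by camera, and 0.557 for both with an estimated correlation). These pathways share members, among them EHHADH, ECI2, ACSL3 and HADH. HIBADH, of valine breakdown, fell from 70.2 ± 4.60 to 18.8 ± 0.230 CPM.

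Most tested genes of cilium assembly that changed fell. In the term cilium assembly 121 of 212 genes fell and 29 rose, and in intraciliary transport particle B 15 of 17 fell and 1 rose, with a median log2 fold change of −1.34. Their camera adjusted p-values were 0.000336 and 0.00133 (Benjamini-Hochberg), and 0.797 for both with an estimated correlation. IFT88 went from 43.7 ± 1.77 to 9.28 ± 1.30 CPM, IFT74 fell by 2.51 and MKS1 by 2.43 on the log2 scale. Aminoacyl-tRNA biosynthesis genes fell in 27 of 44 cases and rose in 6, with FARSB, a subunit of phenylalanyl-tRNA synthetase, down from 169 ± 7.18 to 34.7 ± 1.13 CPM. Proteasome genes fell in 28 of 44 cases and rose in 1, with PSMC6 at −0.96 and PSMD1 at −0.80. Homologous recombination genes fell in 27 of 40 cases and rose in 5, with BRCA1 (overlapping an expressed gene on the same strand, its reads uncertain) at −2.25 and EME1 at −1.99. The camera adjusted p-values of these pathways were 0.000921, 0.000297 and 0.00125 (Benjamini-Hochberg), and 0.557, 0.862 and 0.557 with an estimated correlation. Genes of DNA-binding transcription repressor activity, RNA polymerase II-specific, rose in 150 of 286 cases and fell in 24 (camera adjusted p = 0.000336, and 0.797 with an estimated correlation). Its members NR2F1, ZNF263 and BCL6 rose by 2.11, 2.28 and 3.35.

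The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 10864 changed genes and 6107 of at least 2-fold, and the highest other split 0 of each, so 1 of 10 splits gave as many. For the lists 2 of 10 splits gave as many, the real one with 4 and another (control 1, control 2 and trehalose 3 against the rest) also with 4.

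The osmotic response genes rose with a median log2 fold change of 1.736. Across 15289 genes, log2 fold change rose weakly with GC content (Spearman's rho 0.145, with genes not independent), with medians from −0.219 in the lowest of 5 GC groups to 0.128 in the highest. After a GC correction all 10 called rises of the list were still called and upward, so that trend is not their whole cause. That the rise comes from the osmotic pressure of 200 mM of any solute, rather than from trehalose as such, may hold, but no library with another solute was compared, and the median of 1.736 cannot tell them apart.

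Of 4426 tested genes below 0.5 CPM in the controls, 1482 (33.5%) rose and 88 fell. Without the count filter, 1764 of 19764 listed genes of that level (8.93%) rose, so the shares among tested genes are inflated. Choosing genes that are low in controls favours rises, and the mirror choice, 3623 genes low with trehalose, gave 502 falls and 357 rises. Transcription that runs on past the end of an expressed gene may contribute: 341 of 726 such genes (47.0%) rose where an expressed gene ends within 20 kb upstream on the same strand, against 101 of 336 (30.1%) where one starts within 20 kb downstream (odds ratio 2.059, 95% interval 1.55 to 2.74, Fisher's exact p = 1.68e-07 over genes), and the interval lay above 1 in 16 of 17 alternatives, the exception being counts divided by 4 (1.66, 0.154 to 10.5), where 196 of 201 and 47 of 49 genes left by the filter rose; of the 16, the 2 on FPKM rest on 53 and 20 genes (6.38, 1.38 to 34.6). The share did not fall with distance, at 45.9% within 2 kb and 50.0% at 10 to 20 kb. Over every listed gene the shares were 18.6% and 8.55%, with an odds ratio of 2.44 (1.94 to 3.08). Background spread over the genome stays open for part of the rise. Tested genes with no expressed gene within 100 kb rose at 0.618 (0.535 to 0.715) of the share downstream of one, above the bound of 0.5 set beforehand. Over every listed gene, without the count filter, this ratio was 0.367 (0.315 to 0.426), from shares of 6.82% and 18.6%. Blood or immune cells as the source of CD14 stay open. LYZ, TYROBP, FCER1G and HBB reached at most 0.775 CPM in a trehalose library. That is under 2.16 CPM, the bound taken from the mean CD14 level of 10.8 CPM. These markers were picked after the results were seen, and the count filter had already left them out, so the test could not decide. ITGAM, HBA1 and HBA2 of the same list reached 8.38, 8.37 and 7.48 CPM with trehalose.

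The replication-dependent histone genes rose with a median log2 fold change of 1.57 (95% bootstrap interval 0.79 to 2.82). The bootstrap intervals of this paragraph resample the genes of a set, not the libraries. They show the spread between members and not the error of the treatment effect. Weaker poly(A) selection in the trehalose libraries could contribute: 58 other genes of RNA classes without a poly(A) tail had a median of 0.596 (0.171 to 0.886), an interval that includes 0.787, the bound set beforehand from the histone median; the classes differed, with medians of 0.723 in 35 snoRNA, 1.28 in 5 snRNA and 0.005 in 18 misc_RNA genes, and 9 of the 58 genes rose. More cells in S phase cannot be told apart either, since the G1/S list had a median of −0.323 with an interval of −0.77 to 0.062 that reaches past 0, the bound of that test. Against it, 13 of its 25 genes fell and 5 rose (fry downward, Benjamini-Hochberg adjusted p = 1.32e-05, run in 1 setting only; camera adjusted p = 0.110, and 0.0158 to 0.509 over 14 camera alternatives), and in DNA replication 20 of 36 genes of the KEGG pathway fell and 6 rose (camera adjusted p = 0.0148, and 0.557 with an estimated correlation), while 69 of 133 genes of the GO term fell and 32 rose (camera adjusted p = 0.0566, fry 0.000623). No other biological explanation was tested.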
